A study of Penicillium oxalicum with 6 samples.

How the data were processed

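Digital gene expression tag profiling was performed on mycelia of 3 strains of the filamentous fungus Penicillium oxalicum in 2 media, with 1 library for each strain and medium, 6 in all. Per the labels' protocols, mRNA was captured on oligo(dT) beads and converted to cDNA, which the restriction enzyme NlaIII cleaved at CATG sites. MmeI then released a tag of 17 bp beyond that site, and tags were amplified by PCR between 2 adapters and sequenced as 35-bp Illumina reads. No molecular identifiers are mentioned, so the intervals and floors given here cover counting error only. The tag mapper, the genome build, the annotation version, the rule for tags shared by several genes and the use of strand are not given in the sources used here. Members of multigene families and overlapping genes are uncertain for that reason.

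A single table of the whole series was analysed. It gives tag counts, as deposited and not normalised, for each library, per the file headers, which also state the library total. It also gives deposited TPM values, which here are tags relative to that library total, with no division by gene length: values recomputed from counts and totals match them to within 0.005 TPM, the rounding of the file. The table names genes by identifiers beginning with PDE and gives a best protein match, Gene Ontology terms and KEGG pathways. A product description was present for 2588 of 8902 identifiers, once names such as hypothetical protein were set aside, and gene names used here come from these descriptions. A RefSeq gene table of another P. oxalicum strain, HP7-1 (assembly ASM172317v3), held none of the PDE identifiers and was not used, so no chromosome positions are given. Locus number order stands in for gene order where neighbours are described.

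The glucose columns fill 8902 rows, each with an identifier. The cellulose and wheat bran columns fill 9184 rows, of which 282 carry no identifier. Their values did not follow the identifiers (the report gives the measurements), so results by gene were computed for glucose alone. In cellulose and wheat bran the rows were counted without naming genes, and all 9184 were kept for these counts. The 282 rows without identifier held 1.36% of the library total in the parent, 1.07% in the deletion strain and 1.32% in the complemented strain. The planned tests between media and across media (limma with gene-list tests by camera, or edgeR with the same terms) and the count of genes whose response to the medium differs between strains all need a gene's values in both media, and were not run.

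The comparisons, the size rule, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. A gene stood apart in a library when its value on the TPM + 1 scale was at least 2-fold above both, or at least 2-fold below both, of the other strains in the same medium, with a TPM of at least 10 in any of the 3 libraries. That minimum corresponds to 32.4 to 33.9 tags. The same count for the parent and for the complemented strain served as background. The complemented strain was also compared with the parent by the 2-fold rule. In every comparison of 2 strains the minimum of 10 TPM had to be reached in 1 of those 2 libraries. Ratios of 2 libraries have exact binomial 95% confidence intervals from their tag counts, and shares of a library have exact Clopper-Pearson intervals. A count of 0 was set against a floor of 3 tags, 0.886 to 0.925 TPM, which makes the fold a lower bound with regard to that library alone. The exact lower limit, which also covers counting error in the other library, is lower and is given beside it.

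Since the table holds counts, edgeR's quasi-likelihood test (version 4.0.16, TMM normalisation, Benjamini-Hochberg adjustment, two-sided, threshold 0.05) was added after the data were seen, with DESeq2 (version 1.42.0) as an alternative, both in R 4.3.3. Each set 1 strain's library against the other 2. With the deletion strain alone, the spread comes from the parent and complemented strains, treated as 2 samples of a strain carrying the gene, and the lone library is assumed to vary like them. With another strain alone, the spread contains the deletion strain's own differences, so few calls are possible and those fits are no background. Each library is of a different strain or medium, and no replicate culture is given. The p-values measure only the spread between these libraries, in which strain, culture and technical differences cannot be told apart. In this text rose and fell refer to genes past the edgeR test, and higher and lower to values.

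Gene lists (29, by patterns in the product description) were fixed before the data were examined, and 25 had at least 4 measured members in glucose. For each, the median log2 difference between the deletion strain and the mean of the others was placed among 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these libraries. Terms of the annotation with at least 10 measured members (358) were tested by Fisher's exact test, one-sided in each direction. Named genes were the 8 highest and 8 lowest with a product description, ranked by the smaller of the 2 ratios, the 3 members of each described list with the largest difference, and a fixed set of regulators. Genes outside that rule are said to be chosen after their values were seen. The expression of mtr23B itself, and of abaA, clrB, xlnR and amyR, is not reported here because the descriptions used do not name them.

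The alternatives tried were pseudocounts of 0.1 and 5, no filter and a minimum of 50 TPM, quantile and median-ratio scaling, fold minimums of 1.5 and 4, and unmatched random lists. Added after the data were seen were each control strain alone (also for the list medians), library totals without the most abundant gene, both count tests, and the cellulose and wheat bran rows without those lacking identifiers.

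The procedures were tested on simulated counts drawn from the glucose means and library sizes for the deletion strain against the other 2, with 200 changed genes. With a dispersion of 0.106, the mean between parent and complemented strain, and 5358 genes, the size rule recovered 32.0%, 72.0%, 96.0% and 100.0% of genes planted at 2-, 4-, 8- and 16-fold, and edgeR 6.0%, 46.0%, 86.0% and 94.0%. The size rule called 225 and edgeR 2 of the genes left unchanged. With the median dispersion of 0.03 and 5236 genes, the size rule recovered 32.0%, 94.0%, 98.0% and 98.0% and edgeR 20.0%, 80.0%, 92.0% and 98.0%, with 15 and 0 unchanged genes called. With no gene changed the size rule called 260 of 5378 genes at the mean dispersion, 12 of 5266 at the median and 0 of 5159 with counting error alone. In each simulation all genes shared 1 dispersion and no library was shifted as a whole. The real deletion library differs, its median gene being 0.38 (log2) higher than the mean of the others. The simulated false calls may therefore be too few for the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.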

Results

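Penicillium oxalicum secretes plant-cell-wall-degrading enzymes, and the series asks how transcription depends on mtr23B. The 3 strains were M12, a uracil auxotroph with a mutation in pyrG derived from the wild type 114-2 and taken here as the parent, Dmtr23B, in which mtr23B is deleted, and Rmtr23B, the complemented strain. Mycelia were grown for 20 h at 30 °C in Vogel's medium with 2% glucose, then moved for 24 h to medium with 2% glucose or with 1% cellulose and 1% wheat bran. Each of the 6 combinations has 1 library, so no difference described here has a replicate check. In glucose 2048846 tags of the parent, 2013784 of the deletion strain and 2147854 of the complemented strain were assigned to genes, 60.98%, 60.09% and 63.93% of the library totals. In cellulose and wheat bran the rows held 1889680, 1747696 and 2060019 tags, 58.26%, 51.69% and 60.85% of the library totals. The share was thus lowest in the deletion strain, and TPM values are relative to these totals.

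Some genes of asexual sporulation, the regulator BrlA and 4 genes of conidial pigment, fell in the deletion strain in glucose, while others such as a conidial hydrophobin did not. BrlA (PDE_00087), the transcription factor that starts conidiophore development, fell from 90.5 TPM in the parent to 5.37 TPM, against 89.3 TPM in the complemented strain. The parent exceeded the deletion strain 16.8-fold (95% interval 10.5 to 28.8) and the complemented strain exceeded it 16.6-fold (10.3 to 28.4), with an edgeR adjusted p of 0.0179. The conidial pigment protein Ayg1 (PDE_09452) fell from 752 TPM in the parent and 610 TPM in the complemented strain to 32.5 TPM. A single transcript, PDE_09832, annotated as a structural constituent of the cell wall and chosen after its values were seen, held 82567 TPM in the parent and 166043 TPM in the complemented strain, and fell to 2796 TPM in the deletion strain (edgeR adjusted p 0.0480).

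In the conidial pigment list, 4 of 7 measured members fell and none rose, and the same counts held when adjusted over the list alone (4 fell). Besides Ayg1 these were the scytalone dehydratase Arp1 (PDE_04496), an enzyme of melanin synthesis, the oxidase Arb2 (PDE_09492) and the oxidase Abr1 (PDE_09453), the last named after its values were seen. The parent exceeded the deletion strain 15.6-fold in Arp1 (11.32 to 22.03), 11.4-fold in Arb2 (7.97 to 16.8) and 3.66-fold in Abr1. The 3 other members matched by name are subunits of the ARP2/3 complex and dynactin, which belong to the cytoskeleton, and none of them passed the test. The list of hydrophobins and conidial wall held these same 4 genes and the RodA-like hydrophobin PDE_00021, which stood at 1587, 1388 and 812 TPM in the parent, deletion and complemented strains and did not pass the test (edgeR adjusted p 0.947). Its median difference of -3.58 (log2) lay at percentile 0.03 of random lists, and that of the pigment list, -1.92, at percentile 0.01. Both percentiles rest on the same 4 genes, of which Ayg1 and Abr1 have successive locus numbers, whereas random lists draw genes independently. Of the 3 measured members of the conidiation regulator list, which took in this hydrophobin and LaeA, only BrlA fell. Among other regulators, LaeA (PDE_00584), a global regulator of secondary metabolism, stood at 21.1, 22.1 and 34.8 TPM, and CreA (PDE_03168), the carbon catabolite repressor, at 261, 294 and 178 TPM in the parent, deletion and complemented strains, and neither passed the test (edgeR adjusted p 0.552 and 0.972). WetA (PDE_08333), VeA (PDE_00650) and the pyrG product (PDE_04166) had at most 8 tags in any glucose library, too few for a comparison.

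**Figure D1:**
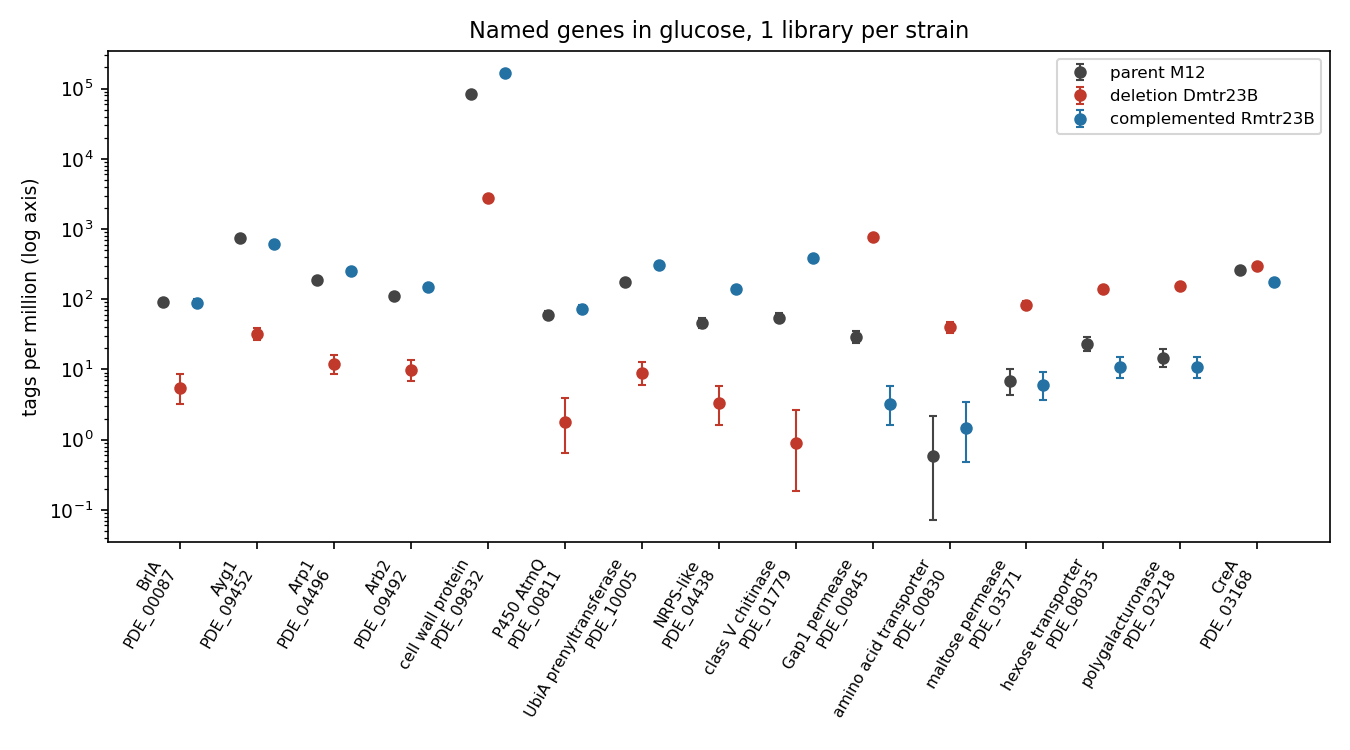
TPM (log axis) of 15 named genes in the 3 glucose libraries, with exact 95% Poisson intervals for counting error. BrlA lies at 90.5 TPM in the parent, 5.37 TPM in the deletion strain and 89.3 TPM in the complemented strain, while Gap1 lies at 29.5, 767 and 3.27 TPM and CreA at 261, 294 and 178 TPM.

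Enzymes of secondary metabolism were also lower in the deletion strain. Of 13 measured members of the backbone enzyme list, 6 fell and 1 rose over all genes, and 8 fell and 2 rose when adjusted over the list alone. The list's name pattern also took in 5 beta-lactamase-fold hydrolases, which are not backbone enzymes. Without them 5 of 8 fell, among them an NRPS-like enzyme (PDE_04438; 46.1, 3.28 and 140 TPM in the parent, deletion and complemented strains) and a UbiA prenyltransferase (PDE_10005; 174, 8.95 and 312 TPM). The hydrolase PDE_09238 fell from 322 TPM in the parent and 1226 TPM in the complemented strain to 2.98 TPM. Of 12 measured cytochrome P450 genes, whose products hydroxylate many small molecules, 6 fell and none rose (7 fell and 1 rose adjusted over the list alone). The AtmQ-like P450 (PDE_00811) was 33.4-fold higher in the parent than in the deletion strain (15.1 to 92.1), and PDE_10010, with 0 tags in the deletion strain, was at least 34.3-fold lower there than in the parent and at least 61.2-fold lower than in the complemented strain by the floor of 3 tags (exact 95% lower limits 27.4 and 49.3). The median differences of these lists were -2.68 and -2.25 (log2), both at percentile 0.00 of random lists. Random lists draw genes independently, whereas PDE_00811, PDE_10005, PDE_10010 and PDE_09238 lie in the runs of neighbouring locus numbers described below. PDE_00803, PDE_09239 and PDE_09761, named next, lie in such runs too. The decreases in this paragraph are therefore partly those of a few linked loci and not independent of each other. Other large decreases were those of a phytanoyl-CoA dioxygenase family protein (PDE_00803), at least 96.8-fold lower than in the parent by that floor (exact 95% lower limit 78.2), a 17-beta-hydroxysteroid dehydrogenase (PDE_09239; 1319, 14.9 and 3159 TPM), an L-ascorbate oxidase (PDE_02128; 2436, 67.7 and 2090 TPM) and 4-hydroxyphenylpyruvate dioxygenase (PDE_09761; 7390, 206 and 9631 TPM), an enzyme of tyrosine breakdown. All of them passed the edgeR test, with adjusted p from 0.0179 to 0.0282.

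Transporters of amino acids and sugars were higher in the deletion strain. Of 12 measured amino acid permeases, 3 rose and none fell (5 rose adjusted over the list alone), and the median difference of 2.04 (log2) lay at percentile 100. The general amino acid permease Gap1 (PDE_00845), a broad-range importer, rose to 767 TPM from 29.5 TPM in the parent and 3.27 TPM in the complemented strain, and the amino acid transporter PDE_00830 rose to 39.7 TPM from 0.60 and 1.49 TPM. The oligopeptide transporter PDE_06899 stood at 94.9 TPM against 21.1 and 1.19 TPM without passing the test (edgeR adjusted p 0.234). Of 16 measured sugar transporters, 3 rose and none fell, over all genes and when adjusted over the list alone, and the median of 1.01 lay at percentile 99.92. A maltose permease (PDE_03571) rose 12.2-fold over the parent (7.94 to 19.5), a maltose transporter (PDE_09994) 8.13-fold (6.76 to 9.85) and a hexose transporter (PDE_08035) 6.03-fold (4.73 to 7.76). The most abundant sugar transporter named here, PDE_09377, chosen after its values were seen, stood at 2708, 9564 and 964 TPM in the parent, deletion and complemented strains (edgeR adjusted p 0.245). Among single genes, a catechol dioxygenase (PDE_05239; 6.25, 117 and 3.87 TPM), an acid sphingomyelinase (PDE_06122; 9.82, 149 and 7.74 TPM), an ABC multidrug transporter (PDE_06542; 17.0, 218 and 17.3 TPM) and an extracellular proline-serine rich protein (PDE_02145; 28.3, 308 and 27.1 TPM) rose with adjusted p from 0.0179 to 0.0191 in edgeR. An aromatic amino acid aminotransferase (PDE_09439) had 37 tags in the deletion strain and 0 in both others, at least 12.4-fold more than in either by that floor (exact 95% lower limit 9.56), and did not pass the test (edgeR adjusted p 0.130).

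Polysaccharide-degrading enzymes differed between lists in glucose. Cellulases were expressed at low levels, at most 43.8 TPM in the parent, while an amylase (PDE_09417), chosen after its values were seen, reached 2314 TPM there. The median differences of cellulases (-0.55, log2), hemicellulases (-0.30) and enzymes of chitin and glucan (-0.09) lay at percentiles 3.77, 2.49 and 3.21 of random lists, and that of amylases (0.94) at percentile 98.25. These lists also differed between the parent and the complemented strain, so the mean of both hides part of the result. Against the parent alone the medians were -0.61 for cellulases, -0.54 for hemicellulases, -1.06 for chitin and glucan and -0.30 for amylases, and against the complemented strain alone -1.27, -0.26, 0.30 and 2.55. The sign of the difference thus depended on the control strain for amylases and for chitin and glucan. Beta-glucosidases, pectinases and secreted peptidases lay at percentiles 28.59, 52.38 and 66.84. None of 7 cellulases and none of 5 beta-glucosidases passed the edgeR test, over all genes or adjusted over the list alone. Cellobiohydrolase II (PDE_07124) stood at 2.38, 4.77 and 24.1 TPM in the parent, deletion and complemented strains. Of 10 hemicellulases 1 rose, an endo-1,4-beta-xylanase (PDE_00752) with 2 tags in the parent, 107 in the deletion strain and 9 in the complemented strain (1 rose and 2 fell adjusted over the list alone). Of 8 pectinases 1 rose, a polygalacturonase (PDE_03218; 14.6, 153 and 10.7 TPM), and 2 also fell when adjusted over the list alone. Among the 8 amylases, PDE_02559 had 45, 0 and 36 tags in the parent, deletion and complemented strains. It is described as an alpha-glucosidase related to nicotinamidase and annotated only with hydrolase activity, so it may not act on starch. Of 17 secreted peptidases 1 fell (2 adjusted over the list alone), penicillolysin (PDE_07936; 35.1, 3.58 and 22 TPM). Penicillopepsin (PDE_07927), the most abundant of them in the parent, stood at 11255, 697 and 5013 TPM, with an edgeR adjusted p of 0.0784. Of 14 enzymes of chitin and glucan, 2 fell, also when adjusted over the list alone: a class V chitinase (PDE_01779), with 184, 3 and 1294 tags and 61.2-fold more in the parent (20.6 to 299), and an endochitinase (PDE_04898; 343, 49.5 and 440 TPM).

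Genes of basic cell functions largely stayed below the test's threshold. None passed it among 52 cytosolic and 15 mitochondrial ribosomal proteins, 29 genes of oxidative phosphorylation, 17 of the proteasome, 20 of endoplasmic reticulum folding and secretion, 12 of glycolysis, 8 of pyrimidine synthesis and 5 histones. This held over all genes and adjusted over each list alone. Members were matched by name, and not all of them belong. The pyrimidine list took in an rRNA and a tRNA pseudouridine synthase (PDE_02298 and PDE_04178), which act on RNA. The cytosolic ribosomal list took in a 50S ribosomal protein (PDE_03914), and the tricarboxylic acid list a homoisocitrate dehydrogenase (PDE_05183). Medians of these lists ranged from 0.14 (log2) for the proteasome, at percentile 14.84, to 0.96 for the histones, at percentile 96.29, beside a median of 0.38 for all measured genes. After scaling to the median ratio the proteasome median was -0.24, that of oxidative phosphorylation -0.07 and that of the cytosolic ribosomal proteins -0.02, so these directions depend on the scaling. By the size rule 4 genes of endoplasmic reticulum folding and secretion were higher and 1 lower, and 2 each of glycolysis and the histones higher. Under median-ratio scaling these were 1 higher and 2 lower, 0 and 0. Of the heat shock and oxidative stress genes 4 were lower and none higher by size. Among them was the 30-kD heat shock protein PDE_00175 (1016, 37.6 and 241 TPM in the parent, deletion and complemented strains). Of 10 tricarboxylic acid cycle matches none passed over all genes and 1 rose adjusted over the list alone, 3-isopropylmalate dehydrogenase (PDE_00542), which belongs to leucine synthesis. Of 28 heat shock and oxidative stress genes 1 fell, also adjusted over the list alone, the heat shock protein PDE_02505 (315, 41.5 and 252 TPM). Of 27 methyltransferases 1 fell (2 adjusted over the list alone), the O-methyltransferase PDE_01069 (29.8, 2.39 and 26.2 TPM). Of 4 measured regulators of lignocellulase genes 1 fell, also adjusted over the list alone, and it was BrlA.

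Over all 5756 genes with at least 10 TPM in any glucose library, 623 stood 2-fold higher and 450 stood 2-fold lower in the deletion strain than in both others, 1073 in all or 18.6%. The background was 168 genes apart in the parent and 585 in the complemented strain. In the edgeR test 76 genes rose and 195 fell in the deletion strain, all of them also apart by size. With the parent or the complemented strain as the lone library edgeR called 0 genes each, with 34 and 196 at unadjusted p under 0.05, while DESeq2 called 0 and 11. These are no background for the 271 genes, since the spread then contains the differences of the deletion strain. DESeq2 called 76 higher and 325 lower in the deletion strain. The median gene was 0.38 (log2) higher in the deletion strain than the mean of the others, and scaling to the median ratio turned the split from 623 higher and 450 lower into 307 higher and 624 lower. Quantile normalisation gave 413 higher and 539 lower. Of the 623 higher genes 307 remained higher under median-ratio scaling, which lowers every value of the deletion strain against both others, so that lower genes stay lower by construction.

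**Figure D2:**
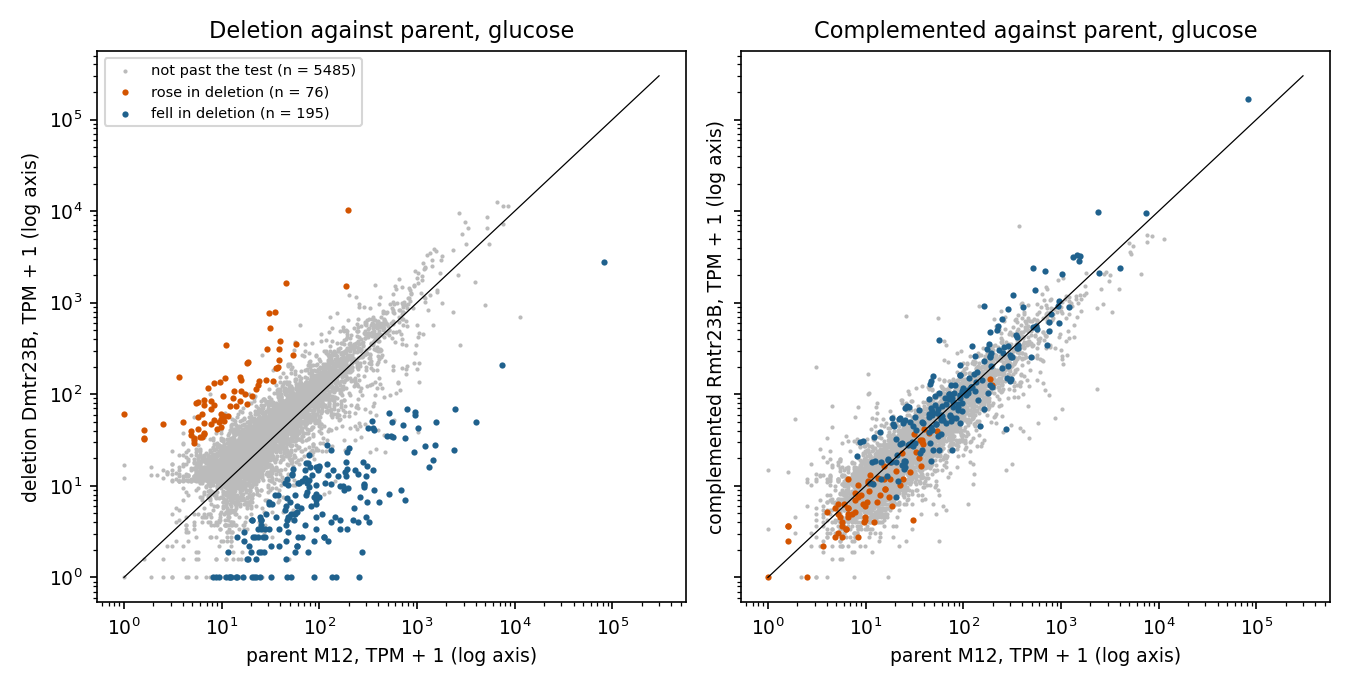
TPM + 1 (log axes) of 5756 genes in glucose, in the deletion strain against the parent and in the complemented strain against the parent, 1 library each, with the line of equal values. Points mark 76 genes that rose and 195 that fell in the deletion strain in the edgeR test, which used both other libraries, so their nearness to the line in the panel of the complemented strain is partly a result of that choice.

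Genes lower in the deletion strain often had neighbouring locus numbers. Of the 450 lower genes, 75 lay in 7 runs of at least 5 with at most 1 other measured gene between, and 1000 random placements gave at most 3 such runs. The longest, from PDE_00789 to PDE_00811, held 20 lower genes of 20 measured, among them nonribosomal peptide synthetases, prenyltransferases and phytanoyl-CoA dioxygenase family proteins, with a median difference of -4.35 (log2), and 18 of the 20 fell in the edgeR test. The run from PDE_09228 to PDE_09246 held 17 lower genes, with a median of -6.21, including matches to stcQ and to AFLR, which in aspergilli belong to sterigmatocystin and aflatoxin synthesis, and 14 fell. The run from PDE_09999 to PDE_10010 held 12, with a median of -3.76, including the UbiA prenyltransferase and a geranylgeranyl pyrophosphate synthetase match (PDE_10001), and 11 fell, that match not among them. These runs were looked for after the data were seen, and locus number order is only a stand-in for position.

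**Figure D3:**
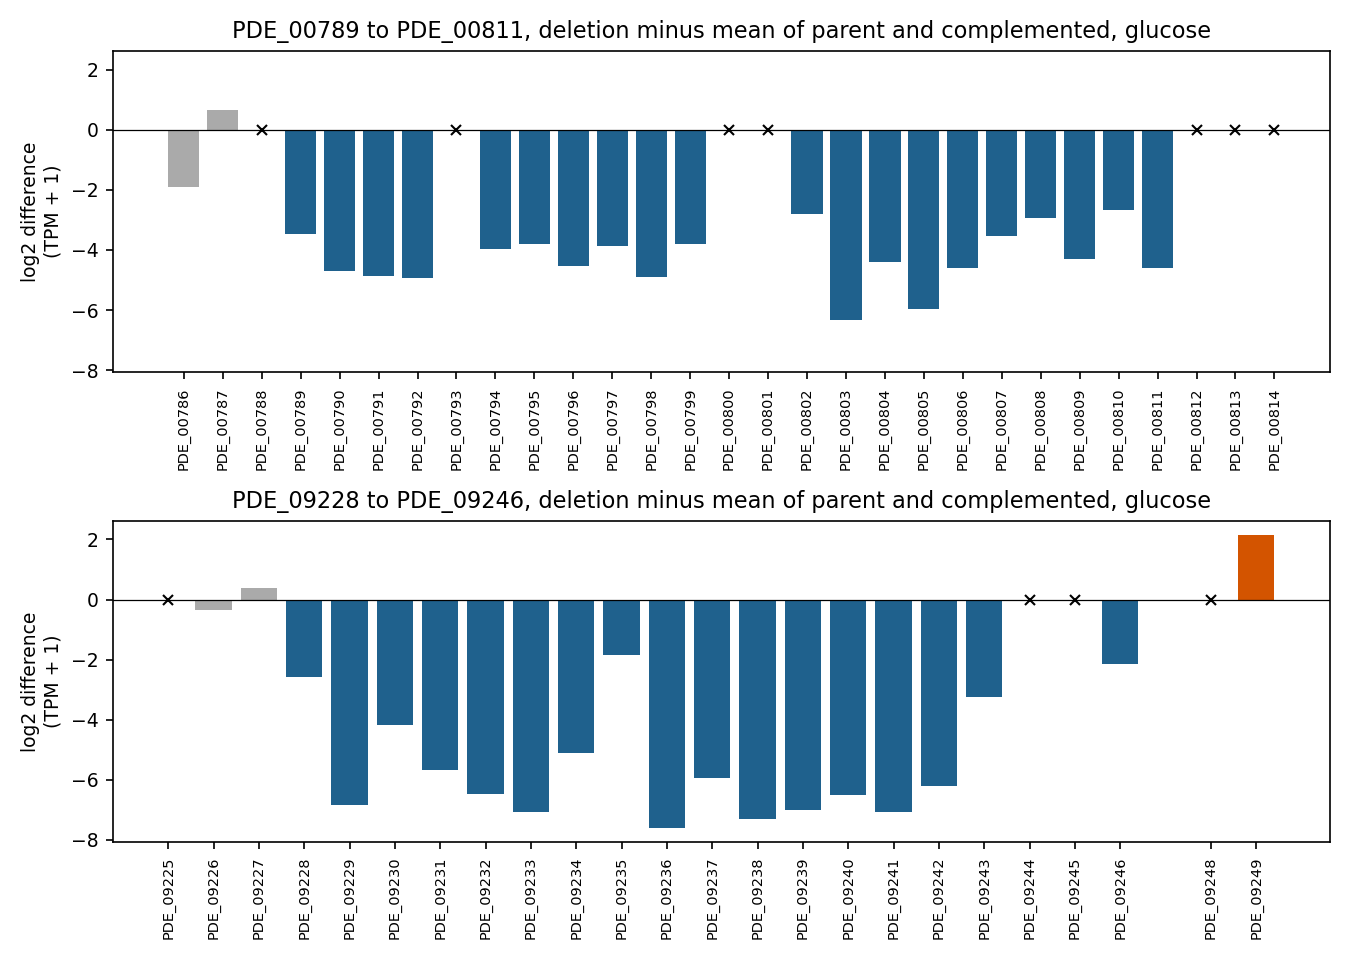
Difference between the deletion strain and the mean of the parent and complemented strains (log2, TPM + 1) in glucose, by locus number, for the 2 longest runs with 3 loci on either side. Blue bars are genes 2-fold lower and orange bars genes 2-fold higher in the deletion strain than in both others, grey bars are other measured genes and crosses are genes below 10 TPM in all 3 libraries, drawn at 0 with no value. The medians of the runs are -4.35 and -6.21.

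The complemented strain was compared with the parent in glucose, the question being how far reintroduced mtr23B restored the parental profile. Of 817 genes 2-fold higher in the deletion strain than in the parent, 682 had the complemented strain within 2-fold of the parent, and 623 were also 2-fold higher than in the complemented strain (76.3%). Of 572 genes 2-fold lower, 375 had the complemented strain within 2-fold of the parent, and 409 were also 2-fold lower than in the complemented strain (71.5%). The rest of the 450 genes lower than in both others reached 10 TPM in the complemented strain alone, so they do not enter the comparison with the parent. These counts reuse the parent's or the deletion strain's library on both sides, so the overlap is not independent of the selection. BrlA differed little (0.987-fold, interval 0.838 to 1.16), and so did Abr1 (1.18-fold, 0.962 to 1.45), and none of the 7 genes of the conidial pigment list differed 2-fold, while PDE_09832 was 2.01-fold higher in the complemented strain. Starch-degrading enzymes were lower there than in the parent: 5 of 8 amylases were at least 2-fold lower and 1 was 2-fold higher, and their median of -2.20 (log2) lay at percentile 0.00 of random lists. Glucoamylase PDE_09417 was 20.6-fold (18.6 to 22.9) and alpha-amylase PDE_01201 15.0-fold (13.2 to 17.3) higher in the parent, and both, chosen after their values were seen, lay between these levels in the deletion strain at 792 and 471 TPM. An alpha-glucosidase (PDE_04454), chosen in the same way, went the other way, from 64.9 TPM in the parent to 343 TPM. Of 7 cellulases 4 were 2-fold higher and 1 was 2-fold lower in the complemented strain, with a median of 1.84 at percentile 100, though at levels no higher than 24.7 TPM in that strain. Cytosolic ribosomal proteins had a median of 0.37, also at percentile 100, with 4 of 52 2-fold higher, and enzymes of chitin and glucan a median of -0.66 at percentile 0.75.

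In total 236 genes were 2-fold higher and 566 were 2-fold lower in the complemented strain than in the parent, 802 in all. The median gene was 0.15 lower (log2) there, and under median-ratio scaling the split was 350 higher and 436 lower. The 1 library per strain gives no test of this difference.

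In cellulose and wheat bran the values could not be tied to genes. The mean log2 count of a row in this medium had a correlation of -0.0121 across rows with that in glucose, within the range of 100 random shuffles of the rows (-0.0292 to 0.0267). Rows annotated to the ribosome, the proteasome and oxidative phosphorylation had median rank percentiles from 81.9 to 91.7 in the 3 glucose libraries and from 42.2 to 56.5 in the 3 of cellulose and wheat bran. The 3 columns of this medium matched each other, with correlations of 0.841 to 0.917 across rows, so counts of rows that differ between strains are given without names. Rows are not independent replicates.

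**Figure D4:**
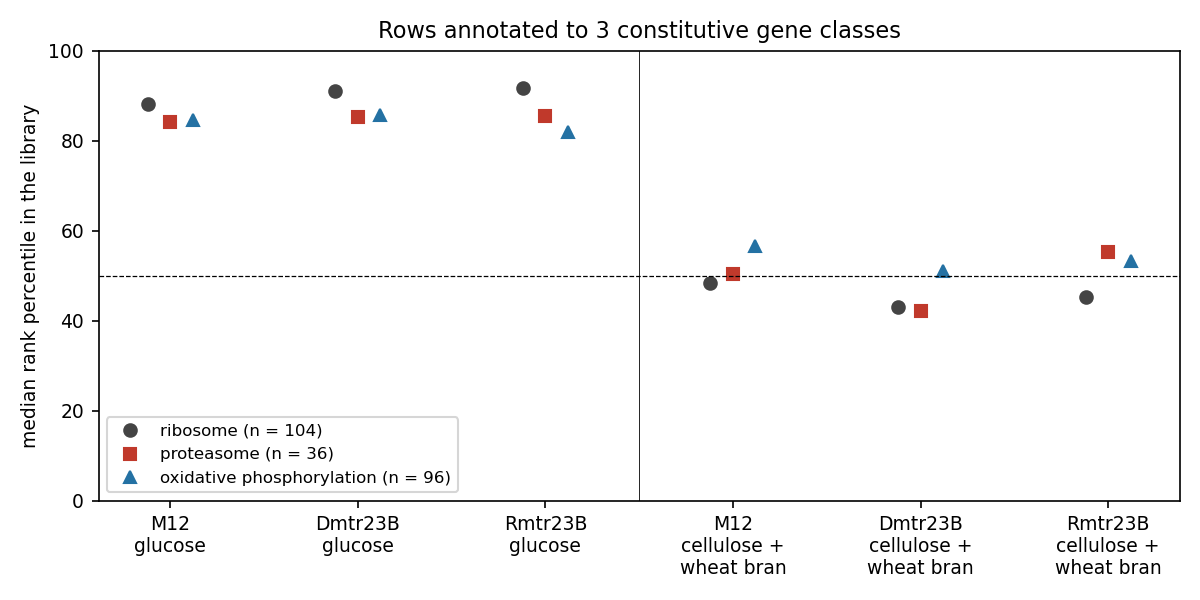
Median rank percentile, in each of the 6 libraries, of rows annotated to the ribosome (104), the proteasome (36) and oxidative phosphorylation (96), with the dashed line at 50. The values lie between 81.9 and 91.7 in glucose and between 42.2 and 56.5 in cellulose and wheat bran.

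Of 5810 rows with at least 10 TPM in any library of this medium, 497 were 2-fold higher and 524 were 2-fold lower in the deletion strain than in both others, 1021 in all or 17.6%. Quantile normalisation turned this split into 575 higher and 488 lower, and median-ratio scaling into 580 higher and 462 lower. The complemented strain stood apart in more rows, 477 higher and 723 lower, and the parent in 252. In edgeR 125 rows rose and 110 fell in the deletion strain, and 0 passed with the complemented strain as the lone library, where 657 were under an unadjusted p of 0.05 and DESeq2 called 72. With the parent as the lone library edgeR called 0 rows, 55 were under an unadjusted p of 0.05 and DESeq2 called 2. In these fits too the spread contains the deletion strain. DESeq2 called 70 higher and 106 lower in the deletion strain. Between the complemented strain and the parent 606 rows were 2-fold higher and 957 lower, 1563 in all. The most abundant row of each library was taken separately and need not be the same row in all of them. It took 3.97% of the library total in the parent (3.95 to 3.99), 1.45% in the deletion strain (1.44 to 1.46) and 4.55% in the complemented strain (4.53 to 4.58), with exact binomial intervals. In glucose PDE_09832 took 8.26% (8.23 to 8.29) and 16.6% (16.6 to 16.6) in the parent and complemented strains.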

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

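The tests of row order were chosen after the mismatch had been seen, and no other pattern is weighed in this part. The rows that carry values for cellulose and wheat bran but no identifier held 124764 tags over the 3 libraries, far above the floor of 3 tags per library, in rows that no comparison by gene uses.

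Values of the cellulose and wheat bran libraries did not go with the gene identifiers. A change of expression with the medium large enough to erase the relation is argued against, because rows annotated to the ribosome, the proteasome and oxidative phosphorylation had a mean median percentile of 49.5 in that medium, the middle of the library, where an expressed class would lie above 60. A search for a constant shift or a reversed order found none. The best correlation of windows of 400 rows was 0.2308, below the highest of 20 shuffles, 0.2662. A planted shift of 300 rows gave 0.958, but between the parent and complemented strains within glucose, over the 8902 rows with identifiers. No shift was planted between media or with extra rows among the others. Whether the search would find such a shift is therefore not known, and a constant shift or a reversed order stays undecided. Rows of these columns in another order than the identifiers stay open as a candidate explanation, with a correlation of -0.0121 inside the range of shuffled rows. No biological explanation other than the medium was tested.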

How the results depend on the processing

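No paired analysis was possible because pairing the media by strain needs a gene's value in both, and the values of the second medium did not follow the identifiers. The limma, camera and medium-response results planned across media, with their alternatives, were not run for that reason. The counts of genes moved with the TPM minimum and the fold minimum by construction. For genes apart in the deletion strain in glucose (1073) they were 565 at a minimum of 50 TPM, 2204 at 1.5-fold and 361 at 4-fold (129 higher, 232 lower), 2077 against the complemented strain alone, and, by tests added after the data were seen, 271 in edgeR and 401 in DESeq2. For the complemented strain against the parent in glucose (802) they were 1336 without a filter, 363 at 50 TPM, 1837 at 1.5-fold and 120 at 4-fold. In cellulose and wheat bran, rows apart in the deletion strain (1021) were 563 at 50 TPM, 2042 at 1.5-fold, 280 at 4-fold, 2665 against the complemented strain alone, 235 in edgeR and 176 in DESeq2, and 994 without the rows lacking identifiers. Rows differing between complemented strain and parent (1563) were 695 at 50 TPM, 2883 at 1.5-fold and 308 at 4-fold. Other pseudocounts and scalings left these 4 totals within 1.5 times. The counts against the complemented strain alone change the control and not a threshold. Against the parent alone the deletion strain differed 2-fold in fewer, 1389 genes in glucose and 1350 rows in cellulose and wheat bran. Of 500 log2 differences of named genes under 5 alternatives, 385 stayed within counting error, 115 moved further and 0 reversed among genes that stood apart. In genes not apart 3 values changed sign under median-ratio scaling, PDE_00021 from 0.29 to -0.105, PDE_03485 from 0.351 to -0.019 and PDE_08297 from 0.328 to -0.066. Of 25 list percentiles, 2 moved by at least 5 points with unmatched lists, by up to 19.0. Genes near 10 TPM rest on about 33 tags, which limits their ratios.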

Other observations

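The tests of 1 abundant transcript, of similar neighbours, of backbone enzymes, of the lower genes of the complemented strain and of its runs were written before their results; the other tests here, including the draws with as many lower genes and the removal of other abundant genes, were chosen after they were seen.

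Annotation terms add further groups in glucose. In Fisher's exact tests across genes, which are not replicates, 12 terms held an excess of genes lower in the deletion strain and 9 an excess of higher ones, after Benjamini-Hochberg adjustment over 716 tests. KEGG's bisphenol degradation had 35 of 115 measured genes lower (30.4%, against 7.8% of all genes), limonene and pinene degradation 24 of 76 and stilbenoid synthesis 15 of 31. These pathways share members: with aminobenzoate and polycyclic aromatic hydrocarbon degradation they cover 210 genes, of which 44 were lower and 24 fell in edgeR. Some of these pathways also had more higher genes than the 10.8% of all genes, without passing adjustment: aminobenzoate degradation 24 of 131 (18.3%), limonene and pinene degradation 15 of 76 (19.7%) and polycyclic aromatic hydrocarbon degradation 14 of 74 (18.9%). Among higher genes, transmembrane transport had 41 of 144 (28.5%, against 10.8%), and carbohydrate transport 9 of 23. In edgeR 13 and 2 of these genes rose, and under median-ratio scaling 28 and 8 genes of these terms were higher. Other terms lost more under that scaling: amino acid transmembrane transport went from 10 to 5 genes, arginine and proline metabolism from 17 to 7, benzoate degradation from 13 to 5 and KEGG's metabolic pathways from 150 to 71.

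Further single genes changed strongly in glucose and were chosen after their values were seen. PDE_05534, matched to a hypothetical protein, rose from 198 TPM in the parent and 127 TPM in the complemented strain to 10329 TPM in the deletion strain. The stress-related match cipC (PDE_06802) rose from 187 and 146 TPM to 1516 TPM.

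More genes were higher than lower in the deletion strain in glucose, 58.1% of those apart. Loss of 1 abundant transcript, which leaves more tags for all others, may account for part of it: with PDE_09832 left out of every library total the share fell to 45.9%, against 57.4% to 59.1% when any of the 10 next most abundant genes was left out instead. That removal lowered the median difference from 0.38 to 0.20 (log2), so a shift remained. Median-ratio scaling gave a share of 33.0%, but it centres the measured genes by construction and decides nothing about scaling by the total of tags. A true rise of many transcripts in the deletion strain stays open and was not tested, as the data hold no external standard.

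Genes lower in the deletion strain followed one another in locus number order. By successive pairs so did higher genes, with 121 pairs, where random placements averaged 67.3 and reached at most 93. Under median-ratio scaling the ratios to chance were 2.74 for lower and 3.07 for higher genes. By runs of at least 5 the higher genes did not exceed chance, with 2 runs, where 1000 random placements gave up to 4. Among successive pairs of lower genes 1.5% had the same best match or description, which argues against tags shared between adjacent similar genes only. Similar genes further apart in a run are not covered, such as PDE_00792, PDE_00794, PDE_00803 and PDE_00806, which share a description. A description also does not measure identity of a tag, so sharing beyond adjacent genes stays undecided. Chance placement is argued against by 137 successive pairs of lower genes, where 10000 random placements averaged 35.1 and reached at most 60. Co-variation of neighbours between any libraries stays open: the ratio to chance was 3.90 (3.28 to 4.61) for these genes and 1.76 for genes lower in the complemented strain, which by the bound written beforehand would count against it, but that bound was set aside after genes higher in the parent reached 5.38. Runs of at least 5 genes numbered 7 here and at most 2 in a set of the other strains, which met the bound written against long runs in every set, but the exact 95% Poisson interval of 2, 0.242 to 7.22, holds 7 and leaves it undecided. Clusters of secondary metabolism are a candidate explanation, with 6 of 13 listed backbone enzymes within 5 locus numbers of a run, or 5 of 8 without beta-lactamase matches, where draws with as many lower genes had 95th percentiles of 3 and 3 and highest values of 7 and 5, though 4 of these enzymes lie in a single run and such draws take genes as independent.

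In the run from PDE_09228 to PDE_09246, the genes from PDE_09229 to PDE_09241 also formed the 1 run of genes 2-fold higher in the complemented strain than in both others, with 11 genes. PDE_09236, chosen after its values were seen, stood there at 2368 TPM in the parent, 23.9 TPM in the deletion strain and 9747 TPM in the complemented strain.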
